A study of Mus musculus with 2 samples.

How the data were processed

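DNase I-seq was used by the submitters to map accessible chromatin in whole thymus from male B6CASTF1/J mice, aged 2 months per the labels. B6CASTF1/J is a cross of C57BL/6J and CAST/EiJ. The series holds 2 samples in 1 group, numbered as replicate 1 and replicate 2 by the labels, which number a separate animal for each but give both the same donor identifier; they were treated as separate animals. With 1 group and no treatment, the comparisons are between the replicates and between genes, regions and sequence motifs within them. No test between samples was possible, and the units of every test were genes, peaks or motif matches, so that each test describes these samples only.

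The authors deposited 4 kinds of interval files per sample, all on mm10 per the labels and the deposited file descriptions. The deposited peak lists give a signal score per peak. The scores of a sample were whole multiples of 1 step, as a count scaled by depth would be; the scale factor was not stated. The depth per sample is not stated in the files; a median peak held 214 steps in replicate 1 and 226 in replicate 2. Each sample has a strict list, in which every peak held a position with a false discovery rate of at most 0.001, and a looser list. The deposited FDR tracks give a p-value of the q-value kind (a false discovery rate) per stretch of bases and list only stretches under 0.05. The deposited footprints carry the constant 0.01 and were used as positions only. The aligner, the peak caller and the footprint tool are not given in the sources used here. Reads and alignments were not analysed here, so intervals cover counting error only.

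The strict lists were the main data. Entries of 1 list that overlapped each other were joined (1602 in replicate 1 and 1090 in replicate 2), keeping the highest score. Peaks were shared when they overlapped by at least 1 bp. A promoter was accessible when a peak lay within 1000 bp of an annotated transcription start site (TSS) of the gene, and its value was the highest such score, averaged over the replicates, which can give different peaks of a gene with several TSSs. Genes and TSSs came from GENCODE M21 and sequences from GRCm38.p6, on the 19 autosomes, X and Y. Distal peaks were shared peaks over 1000 bp from any TSS, counted within 50000 bp of any annotated TSS of a gene.

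Before the data were examined, 27 gene lists and 32 motif consensus sequences were fixed. Each list was compared with all other protein-coding genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. List medians of log2 promoter score (pseudocount 1) and of distal peak number were placed among 10000 random lists of the same size, and called outside 2.5 to 97.5%. Motif matches in shared peaks were compared with windows 2000 bp away that overlapped no peak, matched on GC content in 5-point bins, by two-sided Fisher's exact tests adjusted over motifs. Matches inside shared peaks were compared in the same way with matches of the reversed consensus for the share lying in a footprint of both replicates. Shares carry 95% Wilson intervals, and a count of 0 is given with the limit that 3 counts set. Named genes followed a fixed rule: the 8 members with the highest promoter value of the T cell receptor and of the transcription factor list, 4 of every other list, the first 2 members in alphabetical order without a peak, and the 10 genes with the highest promoter value and the 10 with the most distal peaks. The rule also took the 5 highest distal peaks, and the 5 highest and 3 lowest motif odds ratios past the threshold.

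The alternatives changed the overlap (50% reciprocal), the peaks (the 50000 highest of each replicate, or the looser list), the promoter window (500 and 2500 bp), the TSS (the gene's 5' end only), the background genes (matched in 10 bins of CpG number within 500 bp of the 5' end), the pseudocount (0.1), the reach (25000 and 100000 bp), the GC matching, the footprint overlap and the replicates, each left out in turn. The steps were tested on simulated data. The overlap step found the implanted 79.9% of peaks. With a background of 59.0%, lists of 20 genes set to 95% were called in 10 of 10 cases, lists set to 80% in 0 of 10, to 40% in 2 of 10 and to 20% in 10 of 10. The motif step called 3 of 3 implanted motifs and 0 of 29 others, and the footprint step 5 of 5 and 1 of the others. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0, matplotlib 3.10.9, bedtools 2.31.1 and samtools 1.23.1 were used.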

Results

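Chromatin accessibility was measured by DNase I-seq in the thymus of male B6CASTF1/J mice, in 1 group of 2 replicates. Replicate 1 had 63832 strict peaks and replicate 2 had 67929, which came to 62230 and 66839 after overlapping entries were joined. The peaks covered 14.8 Mb and 14.1 Mb, with a median width of 205 bp and 200 bp and a median score of 1.59 and 1.37. The number of sequenced cuts is not stated in the files. Scores are the submitters' signal values, and values of a gene are means ± SD over n = 2 replicates.

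The first comparison asks how far the accessible regions were shared between the animals. In replicate 1, 83.8% of peaks (95% Wilson interval 83.5 to 84.1%) overlapped a peak of replicate 2, and in replicate 2, 79.8% (79.5 to 80.1%) overlapped one of replicate 1. The shared peaks formed 51709 regions. Strong peaks were nearly all shared: 99.7% and 98.3% in the highest score quartile, against 58.3% and 47.6% in the lowest. Peaks found in 1 replicate alone had a median score of 0.704 in replicate 1 and 0.632 in replicate 2, and 54.4% and 44.6% of them were in the looser list of the other replicate. Across shared regions, which are not independent replicates, log2 scores had a Pearson correlation of 0.944 and a Spearman correlation of 0.928. The median log2 difference, replicate 2 minus replicate 1, was -0.22 with an SD of 0.46, and 3.45% of regions lay more than 2-fold from that median.

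The location of peaks was compared with the make-up of the genome. Regions within 1000 bp of a TSS held 39.6% of peaks in replicate 1 and 40.7% in replicate 2, while they make up 5.88% of the genome, a 6.74-fold and 6.92-fold excess. Introns held 30.5% and 29.6% of peaks (37.3% of the genome), intergenic sequence 25.2% and 25.3% (53.7% of the genome), and exons 4.74% and 4.39%. Of the shared regions, 29398 were distal and 22311 lay at promoters. Promoter regions had a median score of 3.64 and 2.81 in the replicates, and distal regions 1.46 and 1.42.

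The share of genes with an accessible promoter was compared between each list and all other genes. Of the 8 lists of T cell genes, 4 had a higher share (T cell receptor, T lineage transcription factors, early double-negative and double-positive), 1 a lower share (effector genes) and 3 did not pass the test. Of 21938 protein-coding genes, 12935 (59.0%) had an accessible promoter in both replicates, 239 in replicate 1 alone and 353 in replicate 2 alone. Among the 27 gene lists, 8 had a higher share than other genes, 8 a lower share and 11 did not pass the test. Over all genes, the shares per replicate were close to the 59.0% in both, with 60.1% accessible in replicate 1 and 60.6% in replicate 2. For some lists they were further apart. Macrophage and monocyte genes stood at 12.5% in both replicates and 31.25% in replicate 2, and endothelial genes at 25% in both and 43.75% in replicate 1.

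All 21 T lineage transcription factors had an accessible promoter in both replicates (Fisher's exact adjusted p = 0.000167). The highest were Ets1 at 16.8 ± 2.40 (chromosome 9, 32695841 to 32696100 in replicate 1, over a TSS) and Egr1 at 15.97 ± 7.35. Nfatc3 had 12.5 ± 1.36. Gata3, which directs CD4 lineage development, had 10.9 ± 0.838, in an intron. Satb1 had 10.3 ± 2.29, Bach2 9.68 ± 1.49 (different peaks in the replicates) and Id3, an inhibitor of E proteins, 9.39 ± 2.26.

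In the list of the T cell receptor complex and proximal signalling, 23 of 25 genes (92%) were accessible (Fisher's exact adjusted p = 0.00131). The kinase Fyn had 13.1 ± 3.14, the adaptor Lat 12.1 ± 3.50 and the kinase Lck 9.61 ± 2.87 (different peaks in the replicates). The CD3 chains followed, with Cd3g at 8.56 ± 1.52, Cd3d at 6.84 ± 2.15 and Cd3e at 6.08 ± 2.92. The co-receptor gene Cd8a had 8.55 ± 2.30, in a peak at chromosome 6, 71373381 to 71373600 in replicate 1, and Cd8b1 had 8.26 ± 1.56. Trat1 had no promoter peak, and Ptprc, outside the naming rule and chosen after its values were seen, had one in replicate 1 alone.

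Thymocyte stages were described by 3 further lists. Of the early double-negative genes, 15 of 16 (93.8%) were accessible (Fisher's exact adjusted p = 0.00940), with Notch1, the receptor that commits cells to the T lineage, at 7.31 ± 1.62, Gfi1 at 5.54 ± 1.99, Kit at 5.33 ± 0.795 and Notch3 at 4.71 ± 0.043, while Il2ra had no peak. Of the double-positive genes, 14 of 15 (93.3%) were accessible (Fisher's exact adjusted p = 0.0149), among them Spo11 at 8.95 ± 1.95 and Aqp11 at 8.69 ± 2.32. Both calls ended when only the 5' end of each gene counted as its TSS (Fisher's exact adjusted p = 0.0629 and 0.0900), and the double-negative call also with a 500 bp window (Fisher's exact adjusted p = 0.101). Mature single-positive genes were accessible in 12 of 16 cases (75%), which did not pass (Fisher's exact adjusted p = 0.277), but passed against genes of like CpG content (permutation adjusted p = 0.0246). Socs3 had 10.3 ± 0.241 and Klf2, a regulator of thymocyte exit, 8.97 ± 1.58, while Cd40lg and Itgae had no peak.

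Regulatory T cell genes were accessible in 10 of 12 cases (Fisher's exact adjusted p = 0.188). Foxp3, their lineage regulator, had 7.91 ± 0.461 on chromosome X, and Tnfrsf9 had 8.96 ± 2.15. Genes of gamma-delta, innate-like T and NK cells were accessible in 8 of 14 cases (Fisher's exact adjusted p = 1), with Id2 at 12.2 ± 0.547. Effector cytokine and killing genes were accessible in 3 of 17 cases (17.6%; Fisher's exact adjusted p = 0.00200, lower). These were Prf1 at 3.57 ± 0.895, Fasl at 1.63 ± 0.184 and Tbx21 at 1.29 ± 0.233, while Csf2 and Gzma had none. The effector call ended against genes of like CpG content, where the share was 31.98% (permutation adjusted p = 0.332).

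Markers of other cell types, some of them of other organs, were counted in the same way. No promoter of 15 granulocyte and mast cell genes was accessible in both replicates, which allows a share of up to 20% (Fisher's exact adjusted p = 2.11e-05), and none of 16 hepatocyte genes was, allowing up to 18.75% (Fisher's exact adjusted p = 1.73e-05). Macrophage and monocyte genes were accessible in 2 of 16 cases (Fisher's exact adjusted p = 0.00118), among them Itgam, whose replicates scored 1.37 and 1.13. Fibroblast, endothelial, muscle and germ cell genes were each accessible in 4 of 16 cases (Fisher's exact adjusted p = 0.0149 for each), with Col1a1 at 3.82 ± 0.260, Vwf at 3.35 ± 0.076, Ckm at 8.07 ± 1.52 and Gdf9 at 16.2 ± 4.11. A peak near the TSSs of neighbouring genes counts for each of them, so these peaks need not belong to the named gene. Against genes of like CpG content, the granulocyte, hepatocyte, endothelial and germ cell calls held and the macrophage, fibroblast and muscle calls ended (permutation adjusted p = 0.207, 0.167 and 0.152). The endothelial call rested on replicate 2: without it the share was 43.75% (Fisher's exact adjusted p = 0.294), and the macrophage, fibroblast and endothelial calls also ended with the looser list (Fisher's exact adjusted p = 0.0963 for each), as the muscle and germ cell calls did with a 2500 bp window (Fisher's exact adjusted p = 0.279 and 0.111).

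The remaining cell types did not pass the test. B cell genes were accessible in 9 of 17 cases (52.9%; Fisher's exact adjusted p = 0.680), with Vpreb1 at 5.26 ± 1.61, Cr2 at 5.08 ± 0.563, Ebf1 at 4.98 ± 0.940 and Pax5 at 4.47 ± 0.558, while Cd79a had no peak. Dendritic cell genes were accessible in 7 of 15 cases (Fisher's exact adjusted p = 0.507), with Bst2 at 7.53 ± 0.848 and Irf8 at 6.82 ± 0.606. Thymic epithelial genes were accessible in 9 of 20 cases (45%; Fisher's exact adjusted p = 0.314). Among them, Ccl25, a chemokine of the thymic stroma, had 11.2 ± 1.46, Ly75 had 10.4 ± 0.709 and Aire, which drives tissue antigens in medullary epithelium, had 4.61 ± 0.874, while Cldn3 and Fezf2 had none. Erythroid genes stood at 5 of 16 (Fisher's exact adjusted p = 0.0547), adipocyte genes and parathyroid and thyroid genes at 3 of 12 each (Fisher's exact adjusted p = 0.0523 for each), and neuron genes at 8 of 16 (Fisher's exact adjusted p = 0.518). The erythroid, adipocyte and parathyroid lists passed as lower under some alternatives, with Fisher's exact adjusted p = 0.0145 for adipocyte and for parathyroid and thyroid genes and 0.0290 for erythroid genes among the 50000 highest peaks. In replicate 1 alone, parathyroid and thyroid genes stood higher, at 5 of 12 (41.7%).

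Every gene of the housekeeping list (16), the cell cycle list (16), the thymocyte apoptosis list (16) and the MHC class I list (14) had an accessible promoter, with Fisher's exact adjusted p = 0.00131 for the first 3 and 0.00200 for MHC class I. Actb had 21.8 ± 7.13, Mcm5 17.5 ± 6.05, Apaf1, a core part of the apoptosome, 21.1 ± 5.26, and Bcl2l11, which mediates deletion of thymocytes, 13.7 ± 2.48. Psmb9 and Tap1 shared a peak at 18.9 ± 5.21. MHC class II genes were accessible in 7 of 13 measured cases (Fisher's exact adjusted p = 0.811), with H2-DMa at 16.8 ± 4.25 (different peaks in the replicates) and H2-Ab1 at 4.97 ± 0.169, and no peak at Ciita or Cd80. Against genes of like CpG content the apoptosis call held and the housekeeping, cell cycle and MHC class I calls ended (permutation adjusted p = 0.0640, 0.293 and 0.0574).

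**Figure D1:**
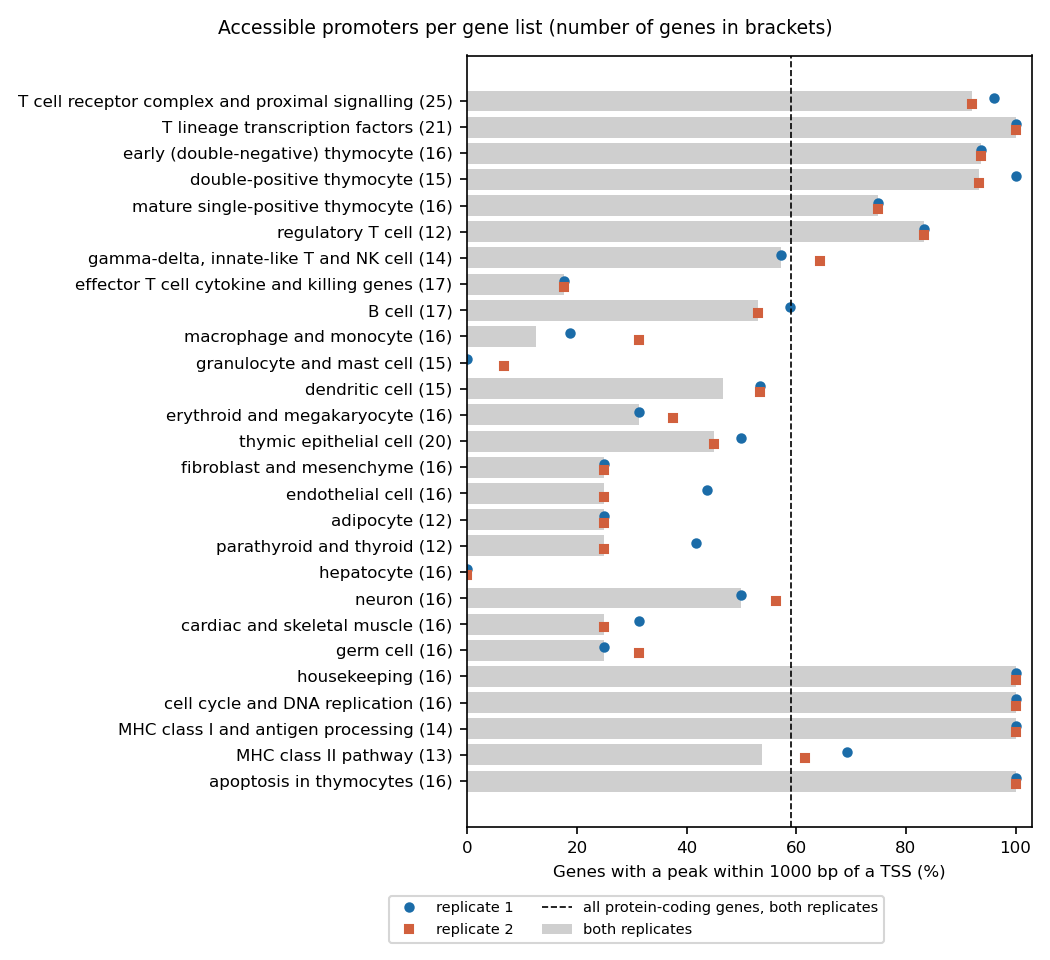
Share of each gene list with a peak within 1000 bp of a TSS, in percent; bars are genes accessible in both replicates, points are single replicates, and the dashed line is the share of all protein-coding genes. T lineage transcription factors stand at 100%, and hepatocyte genes at 0 of 16.

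The height of promoter peaks was compared between each list and 10000 random lists of the same size. Housekeeping (percentile 100), MHC class I (99.9), cell cycle (99.8), apoptosis (99.8) and T lineage transcription factor genes (97.75) had higher median log2 scores. No list could be called lower, since a median of 0, the lowest value, stood at percentiles of 4.87 to 9.61. The median log2 score was 2.97 for the transcription factors, with an SD of 0.25 between replicates, against 1.55 for random lists. T cell receptor genes stood at percentile 86.5 and double-positive genes at 84.7. Among genes with an accessible promoter alone, the housekeeping list remained higher, the transcription factors stood at percentile 52.5, and the double-negative, regulatory T cell and neuron lists were lower. The highest promoter peak of all genes belonged to Dynlt1b, at 58.3 ± 8.99 (chromosome 17, 6429981 to 6430180 in replicate 1). Hjurp and Trpm8 shared a peak at 40.7 ± 5.88, Sugct and Mplkip one at 30.7 ± 4.42, and Myo10 had 31.8 ± 4.40. Gm21887, Dnpep, Nup107 and Fzr1 lay between 28.3 and 28.6. These promoter peaks were not checked for repeated sequence, so their scores may add up reads from several copies. Gm21887 is the gene nearest to the highest distal peak, in which 0% of 31-base words were unique in the genome.

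Genes of 5 of the 8 T cell lists were surrounded by more distal peaks than random lists. Genes with several TSSs were searched over more sequence, and the random lists were not matched on number of TSSs or gene density. Within 50000 bp of the TSS, random lists had a median of 2 shared distal peaks, while T lineage transcription factors had 8, T cell receptor genes 7, mature single-positive genes 6.5 and double-positive genes 6 (percentile 100 for each). Regulatory T cell genes (median 5, percentile 99.8), MHC class II genes (5, 99.8), apoptosis genes (4, 99.3), MHC class I genes (4, 98.9) and housekeeping genes (3.5, 97.8) also passed, and no list was lower. Genes of gamma-delta, innate-like T and NK cells (median 2.5, percentile 80.5) and effector genes (median 2, percentile 60.7) did not pass. The regulatory T cell call ended within 100000 bp (percentile 96.1), the MHC class I call within 25000 bp (96.8), and the housekeeping call in 4 of 5 alternatives, while early double-negative genes (percentile 92.2) passed in 4 of 5. Dendritic cell genes passed within 100000 bp (percentile 99.5) and without replicate 1 (98.6), and cell cycle genes within 100000 bp (97.7). B cell, hepatocyte, neuron, muscle, fibroblast and erythroid genes had a median of 1. Tcf7, the transcription factor that opens the T cell program, had the most distal peaks of all genes, 30, and a promoter value of 5.57 ± 1.45. Ets1, the cyclin gene Ccnd3 and Mid1 each had 26, Prex1 25, Smyd1, a neighbour of Cd8b1, 24, and Cd8b1 23, while Cd8a had 19. Il21r, Gse1 and Cerk also had 23.

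**Figure D2:**
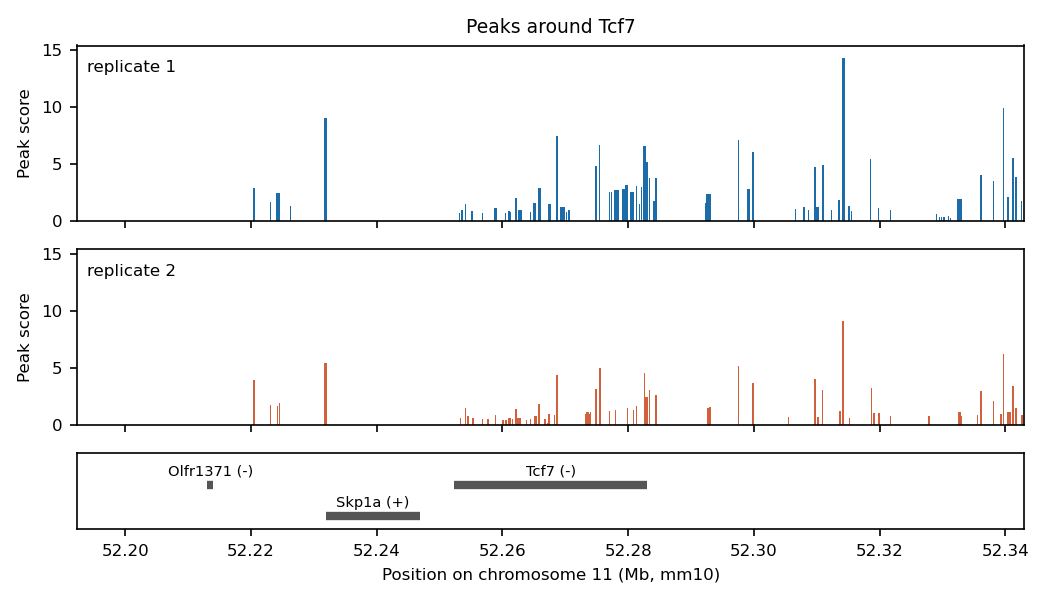
Strict peaks around Tcf7 on chromosome 11, from 52192371 to 52343014 (mm10, in Mb), drawn to scale with the signal score as height, replicate 1 above replicate 2 and protein-coding genes with their strand at the bottom. The region held 74 peaks in replicate 1 and 69 in replicate 2, with highest scores of 14.3 and 9.10.

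The 5 highest distal peaks lay in repeated sequence. The highest, 75.9 ± 20.3 at chromosome X, 169997961 to 169998240, was in an intron of Mid1, and 2 more of the 5 lay in the same gene, at 70.2 ± 17.1 and 48.2 ± 20.4. The fourth, 36.9 ± 9.02 at chromosome 9, 123461881 to 123462120, overlapped an exon of Lars2, and the fifth, 33.0 ± 15.5 on chromosome 3, lay 109640 bp from the nearest protein-coding TSS, that of Gm8797. Of their 31-base words, 39.5% were unique in the genome at the Lars2 peak and 0% at the others, so that scores there can add up reads from several copies.

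The V segments of antigen receptor genes were compared between T cell receptor and immunoglobulin loci. Of 144 T cell receptor V segments, 55 (38.2%, 95% Wilson interval 30.7 to 46.3%) had a peak within 1000 bp in both replicates, against 48 of 218 immunoglobulin V segments (22.0%, 17.0 to 28.0%; two-sided Fisher's exact p = 0.00125, odds ratio 2.19). The shares were 44 of 113 at Tra and Trd, 8 of 22 at Trb and 3 of 9 at Trg. All immunoglobulin peaks were at Igh, where 48 of 113 segments (42.5%) had one, against 0 of 100 at Igk, which allows up to 3%, and 0 of 3 at Igl. The Igh share alone did not differ from that of T cell receptor V segments (two-sided Fisher's exact p = 0.523, chosen after the values were seen), so the difference rests on Igk. The peaks were not placed alike. Their median centre lay 427 bp from the segment's 5' end at Igh, inside or past the segment, and -39 bp, just upstream, at T cell receptor loci. Like shares therefore do not mean like promoters. Olfactory receptor genes had a peak in 13 of 1135 cases (1.15%) and vomeronasal genes in 1 of 331 (0.302%), Vmn1r4, named after its value of 9.35 was seen. Whether such peaks belong to a neighbouring gene was not tested. V segments resemble each other: a median of 40.5% of the sequence around T cell receptor V segments was unique, against 66.6% at Igh and 61.4% at Igk. The median was 54.9% for T cell receptor V segments with a peak and 19.9% for those without, so that peaks there can have been missed.

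**Figure D3:**
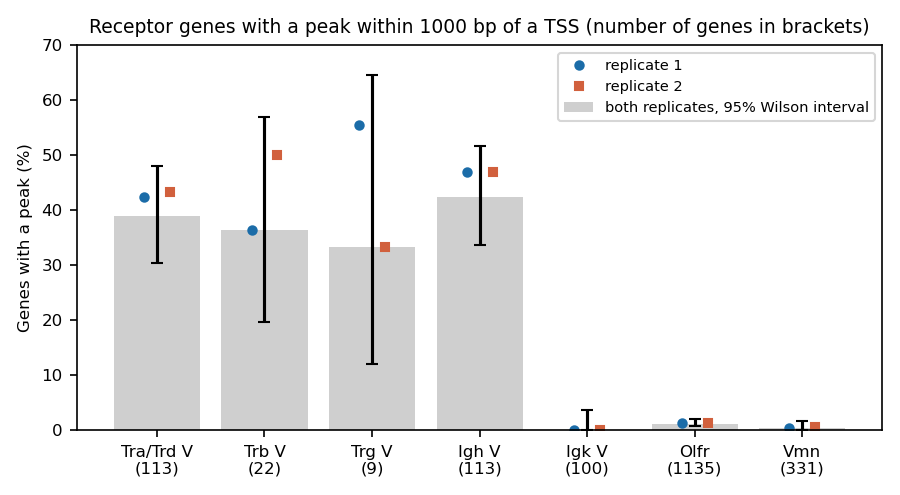
Share of receptor genes with a peak within 1000 bp of a TSS, in percent; bars are genes with a peak in both replicates with 95% Wilson intervals, points are single replicates. Igh V segments stand at 42.5% and Igk V segments at 0 of 100.

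Binding motifs were compared between shared peaks and windows of like GC content that overlapped no peak. In distal peaks, 23 of 32 motifs were more frequent, 3 less frequent and 6 did not pass. CTCF, the insulator factor, stood out, with a match in 14.0% of distal peaks against 0.0997% of windows, an odds ratio of 163. RUNX was found in 6.86% against 2.24% (odds ratio 3.21, Fisher's exact adjusted p = 4.56e-141), ETS in 23.0% against 8.57% (3.19), the E-protein E-box in 33.7% against 22.3% (1.78, Fisher's exact adjusted p = 7.60e-180) and TCF/LEF in 6.36% against 3.94% (1.66, Fisher's exact adjusted p = 4.003e-34). PU.1 (3.70) and C/EBP (3.23), motifs of myeloid factors among others, were as enriched, and GATA stood at 1.13. These 7, and NFY and SP/KLF at promoters, fall outside the naming rule and were chosen after their values were seen. The next highest odds ratios were NFI at 6.00 (Fisher's exact adjusted p = 0.0159), EGR at 5.12 (1.05e-06), the REST motif at 4.23 (5.27e-05) and NRF1 at 4.004 (0.000341), each in under 0.2% of peaks. NFI had 12 matches against 2 in windows, and its call ended with the 50000 highest peaks (4.001, Fisher's exact adjusted p = 0.130). The C/EBP call ended without replicate 2 (1.64, Fisher's exact adjusted p = 0.103). Ikaros (0.854), TEAD (0.775) and EBF (0.730), the B cell factor, were less frequent, with Fisher's exact adjusted p = 0.000504, 0.0118 and 0.00449, but none of the 3 calls held without replicate 1.

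In promoter peaks, 18 motifs were more frequent, 2 less and 12 did not pass. CTCF again had the highest odds ratio, 53.3 (Fisher's exact adjusted p = 6.84e-136), then NRF1 at 26.7 (2.81e-13), CRE/ATF at 6.28 (5.27e-19), EGR at 5.82 (8.46e-05) and C/EBP at 5.52 (1.13e-06). The windows were not matched on CpG number, and the consensus of NRF1, CRE/ATF, EGR, C/EBP, SP/KLF and the REST motif holds a CpG. Their odds ratios, here and in distal peaks, therefore cannot tell the motif from its CpG. NFY (3.57) and SP/KLF (3.18), common in CpG-rich promoters, were also enriched, while the E-box was not (1.05, Fisher's exact adjusted p = 0.179). The E-box did pass without replicate 2 (1.13, Fisher's exact adjusted p = 0.000460) and without GC matching (1.46, Fisher's exact adjusted p = 6.56e-86). YY1 stood at 1.32, and TEAD (0.648) and EBF (0.602) were less frequent. The YY1 and TEAD calls ended without replicate 2 (1.097 and 0.909, Fisher's exact adjusted p = 0.444 and 0.674), and the EBF call without replicate 1 (0.746, Fisher's exact adjusted p = 0.0942). GC matching kept 25086 of the 29398 distal peaks and 8082 of the 22311 promoter peaks. The promoter peaks kept had a mean GC content of 53.4%, against 62.2% in all of them, so the GC-rich promoters are less represented. Without GC matching, EBF turned to 1.12 in distal and 1.76 in promoter peaks, and RUNX and TCF/LEF turned to 0.741 and 0.586 in promoter peaks.

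**Figure D4:**
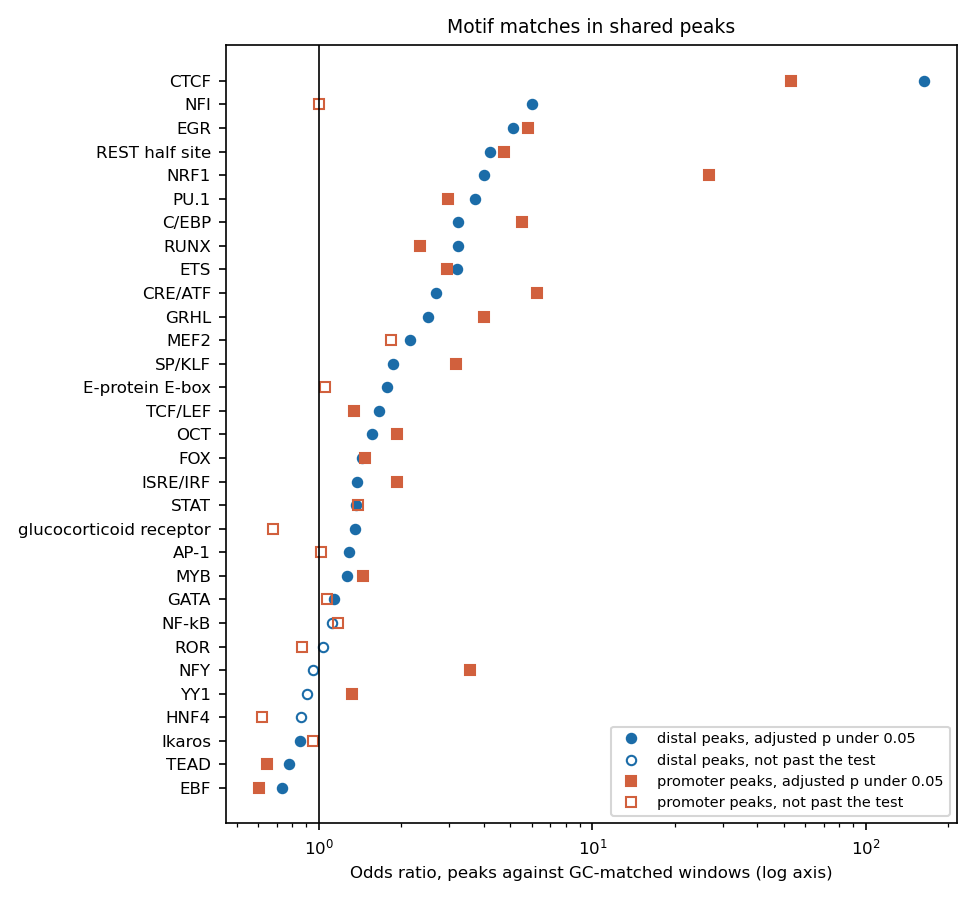
Odds ratios of motif matches in shared peaks against GC-matched windows, on a log axis, for distal peaks (circles) and promoter peaks (squares); filled symbols passed the adjusted test, and HNF1 is left out because no distal window held it. CTCF lies highest, at 163 and 53.3.

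Footprints, short stretches of the kind that a bound factor can shield from DNase I, numbered 291716 in replicate 1 and 295617 in replicate 2. Their median width was 10 bp, and 53.2% and 51.6% overlapped a footprint of the other replicate. Of the peaks, 87.7% and 89.5% held at least 1 footprint, rising from 70.2% and 74.6% in the lowest score quartile to 99.9% in the highest of each. Of the shared regions, 92.1% held a footprint in both replicates, with 94.4% of distal and 89.1% of promoter regions.

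Of 4794 CTCF matches inside shared peaks, 93.8% lay in footprints, against 0 of 8 matches of the reversed consensus, which allows up to 37.5% (Fisher's exact adjusted p = 7.98e-10). NRF1 had a higher share, 96.5% of 395 matches, but with 2 reversed matches it did not pass (Fisher's exact adjusted p = 0.103). Of the motifs, 13 lay in footprints more often than their reversed consensus, 7 less often and 12 did not pass. The 7 include SP/KLF (56.3% against 62.0%), whose reversed consensus is itself a GC box of the same factors and thus no control. Reversal also changes the CpG content of some motifs. The reversed E-box can hold a CpG, which the E-box cannot, and the reversed CRE/ATF consensus lacks the CpG of the original. For the E-box and CRE/ATF, the contrast with the reversed consensus therefore cannot tell the motif from CpG content. CRE/ATF followed at 80.7% against 17.0% (odds ratio 20.5, Fisher's exact adjusted p = 7.68e-111), HNF4 at 14.4% against 1.71% (9.68), EGR at 59.3% against 14.2% (8.79) and the REST motif at 45.9% against 9.68% (7.92). In replicate 1 alone, HNF4 stood at 20.3% against 3.42% and the REST motif at 52.1% against 9.68%. In replicate 2 alone, they stood at 24.6% against 5.13% and 56.2% against 25.8%. TCF/LEF (21.7% against 6.57%) and RUNX (16.4% against 4.96%) were also more often in footprints, while the E-box (11.95% against 20.8%) and MYB (10.9% against 13.5%) were less often there. These 4 were chosen after their values were seen. EBF (odds ratio 0.515), GATA (0.482) and FOX (0.330) were less often there, with Fisher's exact adjusted p = 8.34e-05, 3.20e-07 and 7.98e-10. Without replicate 2 the EBF (0.743) and GATA (0.802) calls ended (Fisher's exact adjusted p = 0.0569 and 0.0674).

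The sex chromosomes carried few peaks. The X held 8.95 peaks per Mb in replicate 1 and 10.6 in replicate 2, against autosomal medians of 24.7 and 26.6 and lowest autosomes of 17.8 and 19.6. Its median score was 1.21 and 0.906, or 0.777 and 0.662 of the autosomal value. The Y held 28 and 43 peaks, 0.318 and 0.488 per Mb, and chromosome 11 was the densest in both replicates. Densities were per Mb of sequence without N, with no correction for repeated sequence, so peaks can have been missed there.

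**Figure D5:**
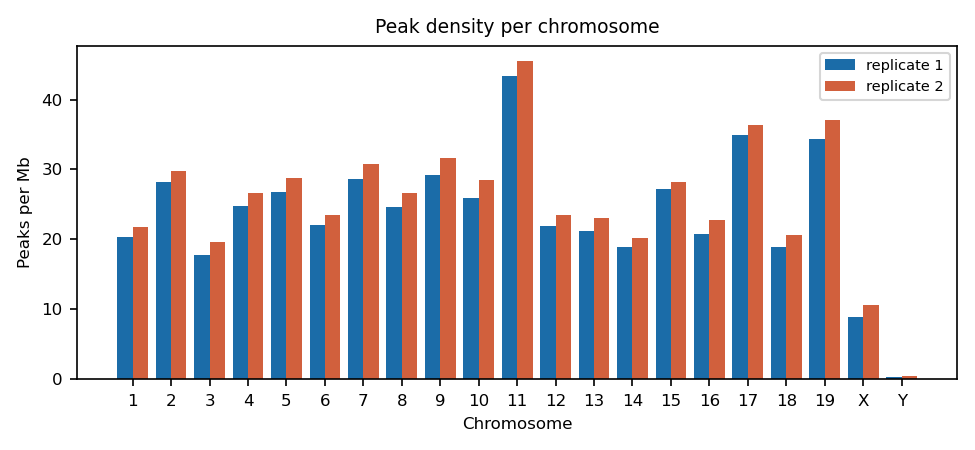
Strict peaks per Mb of sequence on each chromosome for replicate 1 and replicate 2. The X stands at 8.95 and 10.6, below every autosome in both replicates, and chromosome 11 at 43.4 and 45.5.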

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

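The tests in this part were chosen after the main results were seen. No group had enough samples for a test of outlying samples, and 1 group allowed no difference between groups.

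The looser peak lists, which the comparisons do not use as their main data, held signal at promoters that had no strict peak. Of 167 list members without a strict promoter peak in either replicate, 13 had a looser peak in both: Il2ra, Gzma, Ifng, Itgax, Tal1, Pax1, Pax9, Col1a2, Twist1, Adrb3, Casr, Slc17a6 and Ctss. Of 1449 olfactory and vomeronasal receptor genes without a strict peak, 0 had one, which allows up to 0.207%. Other protein-coding genes without a strict peak had one in 346 of 6795 cases, 5.09%, against 7.78% of list members, a difference that did not pass (two-sided Fisher's exact p = 0.152).

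Footprints were also listed outside every peak of their own sample. In replicate 1, 59122 of 291716 footprints lay outside both the strict and the looser list, and in replicate 2, 45554 of 295617.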

How the results depend on the processing

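The alternatives were chosen before the data were examined. Of the 27 lists' promoter shares under 8 alternatives, 180 of 216 values kept their direction and their side of the threshold, 16 lost the call, 11 gained one and 9 changed direction without a call in either setting. Those 9 were B cell genes against genes of like CpG content (52.9% against 34.0%), genes of gamma-delta, innate-like T and NK cells there (57.1% against 48.9%), with the looser list (64.3%) and with the gene 5' end (57.1%), MHC class II genes against genes of like CpG content (53.8% against 34.9%) and with the looser list (76.9%), and both of the latter lists with 1 or both single replicates (ranges 57.1 to 64.3% and 61.5 to 69.2%). The number of lists with a higher share was 6 to 8 (8 in the main setting), and the difference between T cell receptor and immunoglobulin V segments passed its test under every alternative run. For the changes given next, the cause was not tested. With 50% reciprocal overlap, 72.6% and 67.6% of peaks were shared in replicates 1 and 2, and 38.6% and 38.1% of footprints. With the 50000 highest peaks, 84.97% and 86.6% of peaks were shared, the Spearman correlation was 0.908, 43.1% and 44.5% of peaks were near a TSS, and the X to autosome ratios were 0.298 for density (0.380 in the main lists) and 0.930 for score (0.720). With the looser list, 79.5% and 73.9% were shared and 5 lists had a lower promoter share in place of 8. With a 500 bp window, 31.6% and 32.2% of peaks were near a TSS, and with 2500 bp 50.4% and 51.0%. Against genes of like CpG content, 4 lists had a lower share. Among accessible genes alone, 1 list had higher promoter scores in place of 5, and 3 had lower scores, which no list could have in the main setting. There the percentiles of T cell receptor (7.62), double-negative (0.390), double-positive (20.8), mature single-positive (3.62) and regulatory T cell genes (2.33) fell from above to below 50.

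Without GC matching, 5 motifs in place of 3 were less frequent in distal peaks and 15 in place of 2 in promoter peaks. In distal peaks, the odds ratios of GATA (0.853), ISRE/IRF (0.921), OCT (0.774) and EBF (1.12) reversed. In promoter peaks, those of RUNX (0.741), TCF/LEF (0.586), GATA (0.354), AP-1 (0.599), ISRE/IRF (0.634), OCT (0.635), MEF2 (0.524), EBF (1.76), FOX (0.590) and MYB (0.777) reversed. Odds ratios without a call in either setting also changed side of 1. With the 50000 highest peaks these were GATA (0.934), AP-1 (0.938) and NF-kB (0.933) in promoter peaks. With 1 or both single replicates (given as ranges) they were 1 motif (0.954 to 0.970) in distal peaks, GATA (0.902 to 1.09), Ikaros (0.935 to 1.06) and AP-1 (0.940 to 0.993) in promoter peaks, and OCT (0.824 to 1.85), GRHL (0.924 to 1.02) and STAT (0.9004 to 1.23) in footprints. YY1 in distal peaks, without a call in the main setting, stood at 1.02 without replicate 1 and gained a call as less frequent without replicate 2 (0.866, Fisher's exact adjusted p = 0.0321). Without each replicate in turn, 0 to 3 motifs were less frequent in distal peaks. Counting any overlap with a footprint turned AP-1 from 0.697 to 1.00, NF-kB to 1.11 and the glucocorticoid receptor motif to 1.04. Of the percentiles of distal peak number, 116 of 135 kept their direction and their side of the limits, 6 lost the call, 7 gained one and 6 crossed 50. These were B cell genes (61.4 within 25000 bp, 83.2 within 100000 bp and 71.7 to 82.4 with single replicates), and within 100000 bp genes of gamma-delta, innate-like T and NK cells (46.5) and muscle genes (83.7). A stricter footprint threshold was not run, since the footprints carry no score. Depth was not varied; 58.3% and 47.6% of the lowest score quartile were shared.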

Other observations

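The genes of the next paragraph were chosen after their values were seen, and so were the tests of a single scale factor, B cells, repeated sequence and the number of peaks with 1 copy of the X.

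Among list members of many cell types without a promoter peak in either replicate, those with 6 or more shared distal peaks within 50000 bp were the NK receptor gene Klrb1c (13), Mpo (12), Pi16 and Prm2 (11), Tnnt2 (9), Itgae, Pck1 and Plvap (8), Cd40lg, Cldn3, Cx3cr1, Foxn1 and Prtn3 (7), and Cfd, Fcgr1, Hnf4a, Il2ra and Krt8 (6). Joining segments of the T cell receptor had a peak in 11 of 70 cases (15.7%), among them Trbj2-1 and Trbj2-2, which share a peak with a mean score of 3.89. Trbj1-4 to Trbj1-7 had equal scores, as did Traj58 and Traj59, and Traj49 and Traj50, so the segments are not separate cases. In replicate 1, 20 segments had a peak, from 11 distinct peaks, and in replicate 2, 17 from 8. The constant segment Trbc1 had 1.48. Of the immunoglobulin genes beside V segments, Ighj4 had 1.87 and Ighm 0.976.

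Promoter peaks scored higher in replicate 1 than in replicate 2, by a median log2 ratio of 0.36, while distal peaks differed by 0.06. A single scale factor moves all peaks alike and leaves no gap, but the gap was 0.297 (95% interval 0.287 to 0.306 from resampled peaks). Within bins of GC content 0.200 remained, within bins of score 0.245, and within both 63.2% of the gap, so neither accounts for the whole, though each may account for part. Library preparation and a difference between the animals stay open, as untested.

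Igh V segments had peaks in 48 of 113 cases and Igk V segments in 0 of 100. B cells may be a source of the Igh peaks and cannot be told apart from other causes, as 9 of 17 B cell genes (52.9%), among them Vpreb1, Ebf1 and Pax5, were accessible, against 59.0% of other genes (Fisher's exact adjusted p = 0.680) and 34.0% of genes of like CpG content (permutation adjusted p = 0.199), while Cd79a and Ms4a1 had no peak. Repeated sequence leaves the contrast in place: in windows at least 80% unique, 16 of 36 Igh and 0 of 36 Igk segments had a peak (two-sided Fisher's exact p = 3.55e-06). Of 47 Igh V peaks, 40.4% held a CTCF match (27.6 to 54.7%) against 13.6% of distal peaks and 14.5% of T cell receptor V peaks, so CTCF sites remain a possible explanation of part of the peaks, as the interval spans the bound set beforehand. A strain variant against the reference was not tested.

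The X held fewer and lower peaks than the autosomes in these male animals. Promoters on the X had 0.589 of the score of autosomal promoters of like CpG content (0.508 to 0.680 in replicate 1, 0.501 to 0.649 in replicate 2), which may reflect 1 copy but cannot be told apart from other causes, since the intervals extend past the range set for it. Fewer genes alone do not account for the number of peaks, as peaks per gene were 0.514 of the autosomal value. The genes counted were protein-coding genes, with olfactory and vomeronasal receptor genes left out. For 1 copy alone, autosomal peaks at 2 times the score were 1.99 times as dense as X peaks, as a mean of the replicates. Even the lowest autosome was 1.15 and 1.26 times as dense in replicates 1 and 2. The X thus stayed below every autosome, but the lowest autosome did not exceed it by the margin set for rejecting 1 copy alone. This test therefore cannot decide whether 1 copy alone accounts for the whole deficit in number or for part of it. With 1 copy and fewer genes together, over the same genes, the excess was 1.35, between the bounds set beforehand, so the combination stays open.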
